A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

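RNA was taken from mouse LSK cells (2 WT and 2 Anp32b-KO libraries) and from human KU812 cells (2 shNC and 2 shANP32B libraries), per the labels. Total RNA was extracted with Trizol, and 1 ug of it entered library construction by standard Illumina procedures, per the labels' protocols. The submitters' processing notes name HISAT2, TopHat, Cufflinks and DESeq and the genome builds GRCm38 and GRCh38, without roles, order or versions. The counting tool, its strand setting, its treatment of reads shared between genes and the gene annotation are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

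The authors deposited 1 table per library with whole-number counts per gene symbol, not normalized, per the file headers and the values. The 4 mouse tables list the same 17097 genes and the 4 human tables the same 20296 genes. Every listed gene sums to at least 10 counts over the 4 libraries of its experiment, so genes below that sum were not analysed here. Library totals ran from 10549358 to 15683480 counts in LSK cells and from 24416691 to 28209409 in KU812 cells, and a floor of 3 counts stands for 0.191 to 0.284 CPM and 0.106 to 0.123 CPM respectively. Floors and counting intervals cover counting error only. The Spearman correlation of replicates across genes was 0.978 (WT), 0.990 (KO), 0.988 (shNC) and 0.990 (shANP32B). A chi-square test of the counts of each pair gave 51.3, 8.14, 21.3 and 10.5 per degree of freedom in the same order, so no pair differed by as little as sampling noise.

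Each experiment was fitted by itself with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling and the quasi-likelihood test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. CPM values were computed from the deposited counts and the TMM-scaled library sizes. Log2 fold changes are those edgeR reports, slightly moderated by its default prior count. The SE is the size of the unmoderated coefficient (log2) divided by the square root of the F statistic, and the 95% confidence intervals are set around that coefficient. A gene with 0 counts in a whole group has no SE, and its fold was taken against a floor of 3 counts per library. Gene lists of pathways and cell types, fixed before the data were examined, were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01, at least 5 tested members, Benjamini-Hochberg over the lists of an experiment), 32 in LSK cells and 31 in KU812 cells. The same test with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, were the alternatives. With 2 libraries per group the estimated correlation rests on few residual degrees of freedom, which leaves that test little power. A call lost there does not decide whether a list changed. Counts of members are given over all genes tested and adjusted over the list alone. The difference between experiments was tested as an interaction in 1 model over all 8 libraries, on 10855 symbols that are equal in upper case and unique in each species. Correlations across genes used 100000 permutations of the genes.

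The named genes follow a rule fixed before the data were examined. They include ANP32B, ANP32A, ANP32E, CDKN1A and MDM2 in each species, and some genes that the rule takes are not reported here. In each comparison they are also the 10 higher and 10 lower genes with the largest fold change among those past the threshold, with a mean of at least 50 counts and both perturbed libraries on the same side of both controls, or, where fewer than 5 qualify, up to 5 with the smallest unadjusted p, said not to be past it. Predicted genes, pseudogenes and unnamed identifiers were skipped. Up to 4 members with the smallest p represent a list, and the 5 smallest p represent the interaction. Other names are said to be chosen after their values were seen. Mouse coordinates are 1-based on GRCm38 (GENCODE), in which 15068 of 17097 symbols (88.1%) were matched. No human coordinates were used here.

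The tests were tried on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes. In simulated LSK data (14253 genes tested) the edgeR test recovered 7.46% of genes changed 1.5-fold, 44.8% of those changed 2-fold and 83.3% of those changed 4-fold, with 21 false calls (18.9% of all calls). In simulated KU812 data (16069 genes tested) it recovered 41.8%, 85.1% and 92.4% at the same fold sizes, with 12 false calls (7.59%). For the interaction (9922 genes tested) it recovered 92.5% of genes changed 4-fold, with 20 false calls (9.76%). All 3 shares lie above the nominal 5%, and fixing each simulated gene's dispersion at its own estimate may overstate how far genes differ in spread. The simulation gave both groups the same spread, while the real WT pair differed more than the KO pair (chi-square of 51.3 against 8.14 per degree of freedom). The recovered shares may therefore be too high for the real LSK data, in which Anp32b, 3.39-fold lower, did not pass. In simulated LSK data (14290 genes tested) with the p53 target list shifted by 0.5 on the log2 scale, camera called that list and 0 of the others. The simulated genes were drawn independently of each other. This trial therefore does not show how often the preset correlation gives false calls for lists whose genes move together.

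Alternatives fixed beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a replicate block, the list tests named above and leaving out each library in turn, where the lone library of a group is assumed to vary like the others. Added after the data were seen were limma-voom with sample quality weights, library totals only, and LSK cells without immunoglobulin genes.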

Results

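Messenger RNA levels were measured by RNA sequencing in 8 libraries from 2 experiments on loss of ANP32B, an acidic nuclear phosphoprotein that acts as a histone chaperone. In the mouse experiment the cells were LSK cells, bone marrow cells that lack lineage markers and carry Sca-1 and c-Kit, a gate that holds hematopoietic stem cells and multipotent progenitors. They came from C57BL/6 animals that were wild type (WT, n = 2) or knocked out for Anp32b (KO, n = 2). In the human experiment KU812 cells, an established chronic myelogenous leukemia (CML) line with basophil features, carried a control short hairpin RNA (shNC, n = 2) or a hairpin against ANP32B (shANP32B, n = 2). Total counts were 15683480 and 10549358 in the WT libraries, 12117196 and 14085985 in the KO libraries, 28209409 and 25354809 in the shNC libraries, and 25358422 and 24416691 in the shANP32B libraries. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

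The targeted gene was lower in every perturbed library. In LSK cells Anp32b (ENSMUSG00000028333.10, a protein-coding gene on the plus strand of GRCm38 chromosome 4 from 46450902 to 46472657) stood at 762 ± 44.9 CPM in WT and 225 ± 33.6 CPM in KO (SD, n = 2 each), with 12112 and 7655 counts against 2473 and 3559. Its log2 fold change was -1.76 with an SE of 0.17. The values are per gene, and the deleted part of the gene is not given in the sources used here, so the KO counts may come from exons outside it. In KU812 cells ANP32B fell from 268 ± 25.1 to 39.3 ± 1.55 CPM (SD, n = 2 each), a 6.82-fold lower level with a log2 fold change of -2.77 and an SE of 0.12 (adjusted p = 5.18e-08, edgeR quasi-likelihood test). The paralogs Anp32a and Anp32e in LSK cells had log2 fold changes of 0.10 and 0.14, and ANP32A and ANP32E in KU812 cells 0.059 and -0.15, none of them past the threshold. The ANP32A value was -0.079 without the first shNC library.

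**Figure D1:**
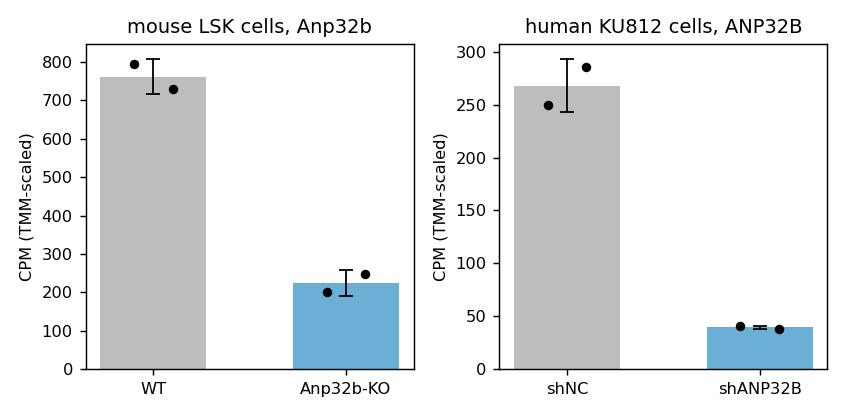
Level of the targeted gene in each library, in TMM-scaled CPM, for LSK cells (left) and KU812 cells (right). Points are libraries, bars the mean of 2 libraries and error bars the SD; both perturbed libraries lie below both controls in each experiment, at 225 against 762 CPM in LSK cells and 39.3 against 268 CPM in KU812 cells.

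The series' title places ANP32B beside p53 in normal and CML stem cells, so the LSK comparison asks how the transcriptome of this stem and progenitor gate differs without Anp32b, p53 targets included. Lower in KO LSK cells, as lists, were markers of mature neutrophils and monocytes, genes of the G2/M phase and mitosis, and markers of stromal and endothelial cells, and the hematopoietic stem cell list was higher. These 4 calls were made with camera at a preset correlation and were lost with an estimated one (adjusted p from 0.632 to 0.975). With 2 libraries per group that second test has few residual degrees of freedom and little power, so the loss does not decide. The 4 calls were lost with fry as well (adjusted p from 0.654 to 0.954). No single gene passed the threshold, Anp32b included, whose adjusted p of 0.148 was the lowest. The genes named from this comparison are therefore given as values.

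The mature neutrophil and monocyte list had a median log2 fold change of -0.48 over 22 tested genes (camera, adjusted p = 1.55e-10 with a preset and adjusted p = 0.632 with an estimated correlation). S100a9, a subunit of the antimicrobial protein calprotectin, had a log2 fold change of -0.58, Lcn2, an iron-binding neutrophil granule protein, -0.70, Ngp, a neutrophil granule protein, -0.69, and Mmp8, a neutrophil collagenase, -0.91. Of the 22 genes 0 passed over all genes, and 7 were lower adjusted over the list alone. The G2/M and mitosis list had a median of -0.26 over 37 genes (adjusted p = 4.59e-10, and adjusted p = 0.975 with an estimated correlation), with 0 genes past the threshold over all genes or adjusted over the list alone. Its members Ccnb1, the mitotic cyclin B1, and Mki67, the proliferation marker Ki-67, stood at -0.59 and -0.38. Of the stromal and endothelial list, median -0.45 over 11 genes (adjusted p = 4.48e-06, and adjusted p = 0.757 with an estimated correlation), 0 genes passed over all genes and 3 were lower adjusted over the list alone. Sparc and Col1a1, both matrix genes, stood at -1.34 and -0.85. The hematopoietic stem cell list had a median of 0.17 over 35 genes (adjusted p = 2.85e-05, and adjusted p = 0.878 with an estimated correlation) with 0 genes past the threshold in either count. Prdm16 and Tal1, transcription factors of hematopoietic stem cells, stood at 0.67 and 0.63, Hoxa5 at 0.52 and Fgd5 at 0.60.

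Another 6 lists passed the preset-correlation test. Markers of T and NK cells (20 genes, median -0.66), basophils and mast cells (20 genes, -0.34), the unfolded protein response (20 genes, -0.17), myeloid progenitors (20 genes, -0.19) and B cells (13 genes, -0.34) were lower, and the erythroid list (25 genes, 0.21) was higher, with adjusted p of 0.00109, 0.0018, 0.00465, 0.0126, 0.0267 and 0.0209 in that order. With an estimated correlation the adjusted p was 0.757 for basophils and mast cells and 0.975 for each of the other 5. None of these lists had a gene past the threshold over all genes or adjusted over the list alone. Gzmb, a cytotoxic granule protease held by both the T and NK list and the basophil and mast cell list, had a log2 fold change of -1.46. Mpo, the myeloperoxidase of myeloid progenitors, stood at -0.54, while Cebpa of the same list stood at 0.44. The antigen presentation genes H2-Ab1 and Cd74 of the B cell list stood at -0.53 and -0.67. The erythroid transcription factor Gata1 stood at 0.52 and Hemgn at 0.48, while Tfrc of the same list stood at -0.28. The endoplasmic reticulum chaperone Calr of the unfolded protein response stood at -0.38. The other 22 lists had adjusted p from 0.0699 to 0.996.

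The first WT library stood apart from the other LSK libraries. Immunoglobulin genes took 1.44% of its counts, against 0.319% in the second WT library and 0.528% and 0.652% in the KO libraries. The 18S ribosomal RNA gene Rn18s-rs5 took 0.0293% of its counts, against 0.851% in the second WT library and 0.51% and 0.30% in the KO libraries. The Spearman correlation across genes was 0.978 between the WT libraries, below the range of 0.980 to 0.989 between WT and KO libraries. Without this library 4 of the 10 lists kept their call, namely neutrophils and monocytes (median -0.51), G2/M (-0.064), stromal and endothelial cells (-0.20) and stem cells (0.12). The medians of those that lost it were 0.16 for T and NK cells, 0.18 for B cells, 0.031 for the unfolded protein response, 0.065 for the erythroid list, -0.14 for basophils and mast cells and -0.086 for myeloid progenitors. Most lists that passed without the first WT library had not passed with all LSK libraries, so leaving it out exchanged most of the calls. The G2/M median, -0.26 with all LSK libraries, lay much nearer 0 without it. Without the first KO library the calls for basophils and mast cells, the unfolded protein response, myeloid progenitors and B cells were lost, and without the second KO library that for the erythroid list, at a median of -0.032. The stem cell median was 0.31 without the second WT library. Beside the list changes, mitochondrial genes took 3.05% and 3.11% of the counts in the WT libraries and 2.13% and 2.31% in the KO libraries.

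The p53 target list had a median log2 fold change of 0.025 and a mean of -0.015 in LSK cells, and the list test pointed down (44 genes tested, adjusted p = 0.885, camera). No member passed over all genes or adjusted over the list alone. The 4 members with the smallest unadjusted p were Pmaip1, which encodes the apoptosis inducer Noxa, at -0.90, Trp53inp1 at -0.46, Zmat3 at 0.66 and Ercc5 at 0.32. Mdm2, the ubiquitin ligase of p53, stood at -0.25. Cdkn1a, which encodes the cell cycle inhibitor p21, had a log2 fold change of -0.76 that came from the first WT library, at 247 CPM against 92.1 CPM in the second WT library and 114 and 86.3 CPM in the KO libraries. Without that library its log2 fold change was 0.12.

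Among the genes with the smallest unadjusted p, none past the threshold, Echdc2 (chromosome 4, 108165437 to 108179308) was read at 1.11 and 15.3 CPM in the WT libraries and at 184 and 186 CPM in the KO libraries, a log2 fold change of 4.59 with an SE of 0.79. Higher values also belonged to Hist3h2ba (2.03), the acyl-CoA thioesterase gene Acot1 (1.06) and the lymphotoxin gene Ltb (0.84). The immunoglobulin segment Ighv1-49 had 0 counts in both WT libraries and 47 and 358 in the KO libraries, at least 15.8-fold higher in the first KO library and 104-fold in the second, against a floor of 3 counts per WT library. Lower values belonged to Chil3, a chitinase-like protein of myeloid cells (-1.75), the inflammasome gene Nlrp3 (-1.10), the interferon-inducible gene Pyhin1 (-1.20) and the immunoglobulin segment Igkv9-120 (-1.85). Immunoglobulin segments form a family of near-identical genes, so the assignment of their reads is uncertain.

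In total, 0 of 14598 tested genes passed at an adjusted p under 0.05 (edgeR quasi-likelihood test), and 657 had an unadjusted p under 0.05, 335 higher and 322 lower, where chance alone gives 730. DESeq2 called 15 genes, Anp32b among them, and limma-voom with sample quality weights 2, where LSK data simulated with no change gave 8 and 2. Without the first WT library 36 genes passed, without the second WT library 830, without the first KO library 5 and without the second KO library 0. With an estimated in place of a preset correlation 0 lists passed, and with fry 0.

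The KU812 comparison asks the same of a CML line. With ANP32B knocked down, the lists of glycolysis and the hypoxia response, DNA replication, mitosis, ribosomal proteins, cholesterol synthesis, DNA repair and the erythroid program were lower. These list calls were made with camera at a preset correlation and were lost with an estimated one (adjusted p from 0.392 to 0.513). Within the basophil and mast cell list EPX, PRG2 and CLC fell while CPA3 and LTC4S rose, and the platelet gene GP1BA rose too. Of 16529 genes tested, 2741 passed at an adjusted p under 0.05 (edgeR quasi-likelihood test), 1244 higher and 1497 lower in shANP32B, among them 460 at least 2-fold higher and 366 at least 2-fold lower. Scaled by library totals only, the split was 1474 higher and 1182 lower.

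The largest falls among genes with a mean of at least 50 counts were in EPX, the eosinophil peroxidase (18.2 ± 0.471 to 0.807 ± 0.114 CPM, SD, n = 2 each; log2 fold change -4.48), HAL, a histidine-degrading enzyme (-4.20), PNCK (-3.91), the hypoxia-induced carbonic anhydrase CA9 (-3.77), the creatine transporter SLC6A8 (-3.65), the chemokine receptor CXCR4 (-3.61), NDUFA4L2, a hypoxia-induced mitochondrial protein (-3.43), TMEM56 (-3.18), ADGRG3 (-3.04) and PITX1 (-3.02). The largest rises were in CHRM1, a muscarinic acetylcholine receptor (0.316 ± 0.160 to 11.5 ± 3.15 CPM, SD, n = 2 each; log2 fold change 5.15), CHST8 (4.60), PPP1R14C (4.27), AATF (3.49), TG (3.15), EYS (3.13), TMEM233 (2.84), SORCS1 (2.83), PTPRS (2.77) and CSF2, the growth factor GM-CSF (2.71). AATF was read at 37.4 and 11.2 CPM in the shANP32B libraries, against 1.22 and 3.17 CPM in the shNC libraries. The adjusted p of these 20 genes lay between 6.85e-07 and 0.00266.

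Of the glycolysis and hypoxia list, 22 of 30 tested genes fell and 0 rose (24 fell adjusted over the list alone), with a median log2 fold change of -0.82 (camera, adjusted p = 9.07e-23 with a preset and adjusted p = 0.392 with an estimated correlation). Besides CA9, the glycolytic enzyme genes PGK1, LDHA and PKM fell by 1.06, 1.00 and 0.83 on the log2 scale, LDHA from 926 ± 76.9 to 464 ± 51.2 CPM (SD, n = 2 each). The median was -1.09 without the second shNC library and -0.55 without the first. Of the cholesterol biosynthesis list 10 of 24 genes fell and 1 rose (14 and 1 adjusted over the list alone; median -0.38, adjusted p = 6.70e-08, and adjusted p = 0.513 with an estimated correlation). INSIG1, a regulator of sterol synthesis, fell by 1.30 on the log2 scale, and the synthesis enzyme gene HMGCS1 by 0.94.

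Both cell cycle lists were lower. Of 42 G1/S and DNA replication genes 25 fell and 0 rose (30 fell adjusted over the list alone; median -0.46, adjusted p = 3.51e-11, and adjusted p = 0.513 with an estimated correlation), with the replication licensing genes CDT1 and MCM6 at -0.79 and -0.70, DTL at -0.79 and the DNA polymerase gene POLD1 at -0.66. Of 38 G2/M and mitosis genes 19 fell and 0 rose (31 fell adjusted over the list alone; median -0.39, adjusted p = 3.51e-11, and adjusted p = 0.392 with an estimated correlation), with the spindle checkpoint kinase genes BUB1 and TTK at -0.85 and -0.83 and CDK1 at -0.68. In the DNA repair list 17 of 34 genes fell and 1 rose (19 and 1 adjusted over the list alone; median -0.39, adjusted p = 2.05e-07, and adjusted p = 0.392 with an estimated correlation), with the checkpoint kinase gene CHEK1 at -0.72 and the Fanconi anemia genes FANCI and FANCD2 at -0.63 and -0.74. Of 14 replication-dependent histone genes 5 fell and 0 rose in both counts, over all genes and adjusted over the list alone (median -0.93, adjusted p = 3.97e-04, and adjusted p = 0.392 with an estimated correlation), with HIST1H1C, a linker histone, at -2.32 and HIST1H2BK at -0.80. Histone genes are near-identical copies, and their reads are uncertain.

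Most ribosomal protein genes fell. Of 29 small-subunit genes 24 fell and 0 rose (25 fell adjusted over the list alone; median -0.42, adjusted p = 6.95e-11, and adjusted p = 0.457 with an estimated correlation), and of 44 large-subunit genes 26 fell and 0 rose (36 fell adjusted over the list alone; median -0.35, adjusted p = 1.61e-10, and adjusted p = 0.513 with an estimated correlation). RPS20, RPS16 and RPS3 had log2 fold changes of -0.65, -0.61 and -0.48, and RPL24 and RPL14 of -0.52 and -0.51. Ribosomal protein genes have many processed pseudogenes, and how shared reads were counted is not given in the sources used here. The list of the ANP32 family and histone chaperones holds ANP32B, the target of the hairpin, so part of its fall was set by the design. It was not tested without ANP32B. In the list of the ANP32 family and histone chaperones, 4 of 20 genes fell and 0 rose in both counts, over all genes and adjusted over the list alone (median -0.15, adjusted p = 7.80e-04, and adjusted p = 0.548 with an estimated correlation), namely ANP32B, NPM1 (-0.48), CHAF1A (-0.42) and NAP1L1 (-0.38), of which CHAF1A and NAP1L1 lost their calls without either shANP32B library.

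Lineage genes moved in both directions. In the erythroid list 16 of 30 genes fell and 1 rose (19 and 1 adjusted over the list alone; median -0.63, adjusted p = 3.51e-11, and adjusted p = 0.392 with an estimated correlation), with the carbonic anhydrase gene CA2 at -1.29, the beta globin gene HBB at -1.23, CA1 at -0.87 and the transferrin receptor gene TFRC at -0.66. In the myeloid progenitor and granule list 4 of 13 genes fell and 0 rose in both counts, over all genes and adjusted over the list alone (median -0.18, adjusted p = 1.75e-04, and adjusted p = 0.392 with an estimated correlation), with MS4A3, a marker of granulocyte and monocyte progenitors, at -2.35, the myeloid transcription factor gene CEBPA at -1.84, CST7 at -1.10 and CLEC12A at -1.20, of which CLEC12A lost its call without either shANP32B library. In the megakaryocyte and platelet list 7 of 18 genes rose and 2 fell (7 and 3 adjusted over the list alone; median 0.29, adjusted p = 0.00417, and adjusted p = 0.513 with an estimated correlation), with the thrombin receptor gene F2R at 1.11, the platelet glycoprotein gene GP1BA at 1.32, PLEK at 0.96 and TIMP3 at -0.90. This list lost its call without the second shNC library, at a median of 0.19. Of 14 mature neutrophil and monocyte genes 4 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.14, adjusted p = 0.0303, and adjusted p = 0.457 with an estimated correlation), and all 4 were low, S100A8 at 6.72 and S100A9 at 3.52 CPM in shANP32B cells, with log2 fold changes of 2.54 and 2.31, followed by CCR2 (1.92) and MMP9 (1.87). CCR2 lost its call without the second shANP32B library, and MMP9 without the second shNC or the first shANP32B library. This list lost its call without the second shNC library, at a median of 0.54, and with limma-voom and sample quality weights (adjusted p = 0.0652).

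The basophil and mast cell list, the lineage KU812 cells resemble, parted into members that rose and members that fell. Of its 21 tested genes 7 rose and 5 fell (11 and 6 adjusted over the list alone), and the list test did not pass (median 0.42, mean -0.036, adjusted p = 0.556, camera). Besides EPX, PRG2, the eosinophil major basic protein, fell from 1641 ± 141 to 587 ± 60.9 CPM (SD, n = 2 each), a log2 fold change of -1.48. CLC, the Charcot-Leyden crystal protein, and SRGN, the proteoglycan serglycin, fell too, with log2 fold changes of -2.69 and -1.88. The following were chosen after their values were seen. IL5RA, a receptor chain of eosinophils and basophils, fell by 0.90 on the log2 scale. The mast cell carboxypeptidase gene CPA3 rose by 1.06, the leukotriene synthase gene LTC4S from 61.6 ± 11.6 to 147 ± 13.9 CPM (SD, n = 2 each; log2 fold change 1.26), and SLC18A2 and IL1RL1 by 0.70 and 0.45. The tryptase genes TPSAB1, TPSB2 and TPSD1 rose by 1.21, 1.26 and 1.47, and as near-identical copies their single values are uncertain.

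**Figure D2:**
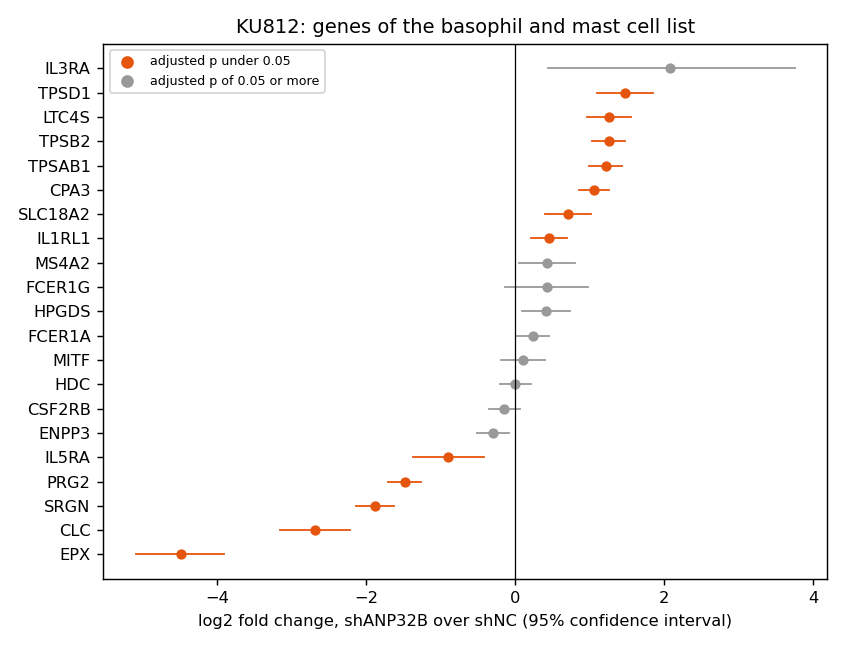
Log2 fold change (shANP32B over shNC, x axis) of the 21 tested genes of the basophil and mast cell list in KU812 cells, with 95% confidence intervals as lines; orange marks an adjusted p under 0.05. The 5 genes that fell lie on the left, from EPX at -4.48 to IL5RA at -0.90, and the 7 that rose, mast cell tryptases and CPA3 among them, lie on the right.

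Of 40 tested p53 targets in KU812 cells 2 rose and 5 fell (5 and 7 adjusted over the list alone). The list had a median log2 fold change of -0.044 and a mean of 0.026, and its test pointed down without passing (adjusted p = 0.579, camera). BTG2, an antiproliferative gene, rose from 52.8 ± 22.8 to 240 ± 95.9 CPM (SD, n = 2 each; log2 fold change 2.18), and PLK3, chosen after its value was seen, rose by 0.65. PLK2, CMBL and CCNG1 fell by 1.34, 0.63 and 0.54 on the log2 scale. MDM2 fell by 0.38 with an adjusted p of 0.0466, a call that was lost without the second shNC library (-0.30), without either shANP32B library (-0.35 and -0.42) and when scaled by library totals only (-0.32). CDKN1A stood at -0.21 (adjusted p = 0.509), not past the threshold, and at 0.089 without the first shANP32B library. In the hematopoietic stem cell list 3 of 26 genes rose and 4 fell (4 and 7 adjusted over the list alone; median 0.012, mean 0.075, test pointing down with an adjusted p of 0.612). CTNNAL1, the stem and progenitor antigen gene CD34 and TXNIP fell by 1.12, 1.83 and 0.83, and ESAM rose by 0.76.

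None of the 13 lists that passed in KU812 cells with the preset correlation passed with an estimated one. That test has little power with 2 libraries per group, so the loss does not decide. With fry 8 lists passed, of which 7 are among these 13. Those that did not pass with fry were the glycolysis, G1/S, cholesterol, erythroid, megakaryocyte and platelet, and ANP32 family lists. Their adjusted p with fry ran from 0.0625 (erythroid) to 0.145 (cholesterol). Beside these changes, mitochondrial genes took 3.05% and 3.81% of the counts in the shNC libraries and 4.59% and 4.58% in the shANP32B libraries. The number of genes past the threshold was 1621 without the first shANP32B library and 1413 without the second.

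**Figure D3:**
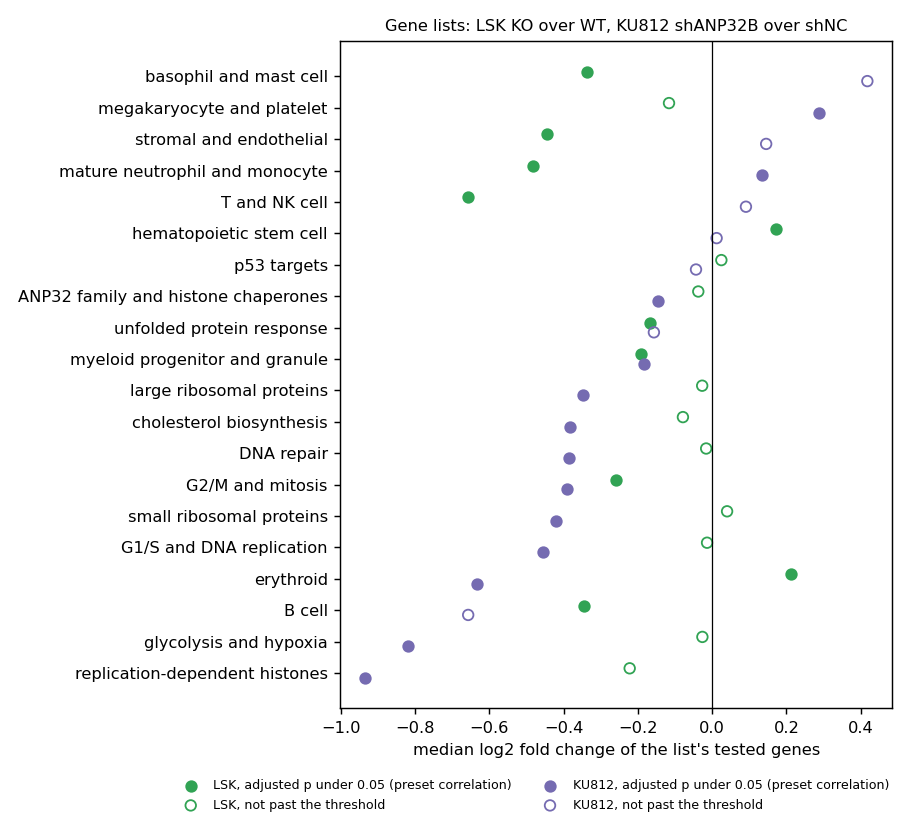
Median log2 fold change (x axis) of the tested genes of each list that passed in at least 1 experiment, and of p53 targets, in LSK cells (KO over WT, green) and KU812 cells (shANP32B over shNC, purple). Filled points passed the list test with a preset correlation; the glycolysis and hypoxia list lies at -0.82 in KU812 cells and -0.026 in LSK cells, and the p53 targets lie at -0.044 and 0.025.

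Whether the change on loss of ANP32B differed between LSK and KU812 cells was tested with an interaction term over genes whose symbols match between the species. Species, the way ANP32B was lowered and cell type all differ between the experiments, so the term does not single out normal against leukemic cells. Of 10771 genes tested, 239 differed (edgeR quasi-likelihood test, adjusted p under 0.05), with the change in LSK cells above that in KU812 cells for 143 and below it for 96. ANP32B was among them, at -1.76 in LSK and -2.77 in KU812 cells (adjusted p = 0.0255), though counts in KO cells may come from exons outside the deleted part. The calprotectin genes S100A8 and S100A9 differed by -3.03 and -2.91 (LSK minus KU812, log2), with fold changes of -0.47 and -0.58 in LSK cells against 2.54 and 2.31 in KU812 cells. The model shares a single estimate of spread per gene across both experiments. The SEs of these differences were 0.24 and 0.26, below those of 0.35 and 0.44 in KU812 cells alone. Their p-values may therefore be too small, as both genes were low in KU812 cells. HIST1H1C, HGF, the hepatocyte growth factor gene, and AFAP1L1 differed by 2.38, 2.54 and 2.12, with log2 fold changes of -2.32, -2.52 and -1.77 in KU812 cells and of 0.082, 0.033 and 0.37 in LSK cells. Of 31 lists 12 differed with a preset correlation and 0 with an estimated one (lowest adjusted p = 0.0865). The glycolysis and hypoxia list, median difference 0.71, had 4 of 27 genes above and 0 below (11 and 0 adjusted over the list alone), and the mature neutrophil and monocyte list, -0.82, had 0 of 13 above and 4 below (0 and 5 adjusted over the list alone). The p53 targets did not differ past the threshold (40 genes, median difference 0.12, adjusted p = 0.646). The count of 239 was 719 without the second WT library, 51 and 38 without the first and second KO libraries, 102 without the first shNC library, and 98 and 53 without the first and second shANP32B libraries.

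Across 9922 genes tested in both experiments, which share no library, the log2 fold changes in LSK and KU812 cells had a Pearson r of 0.0376 (permutation p = 1.40e-04, two-sided) and a Spearman rho of 0.0629 (permutation p = 1e-05, the smallest the 100000 resamples can give). Genes are not independent replicates, so these p-values are too small. Of genes higher in LSK cells at an unadjusted p under 0.05, 31 also rose in KU812 cells at an adjusted p under 0.05. Independent lists give 16.2 (Fisher's exact test, two-sided p = 5.29e-04). Of those lower in LSK cells 35 also fell, where independent lists give 21.3 (Fisher's exact test, p = 0.00327). These p-values treat genes as independent too. Overlap in opposite directions was not counted, so genes that are easier to call in both experiments may add to both overlaps. The r was 0.0181 without the first WT library, 0.0110 without the first KO library and 0.0144 without the first shANP32B library, and did not pass a p of 0.05 in any of them.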

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

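The tests of the first WT library alone, of other cell types, of the scaling between libraries and of the first shNC library alone were chosen only after the results were seen, and the tests of expression level and of chromosome 4 after the patterns were seen but before these tests were run. The changes on loss of ANP32B differed between LSK and KU812 cells, by the interaction test, for 239 genes. The genes with the smallest p were S100A8 (-3.03, LSK minus KU812, log2), HIST1H1C (2.38), HGF (2.54), S100A9 (-2.91) and AFAP1L1 (2.12). By the list test with a preset correlation, 12 lists differed. Their median differences were 0.71 for glycolysis and hypoxia, 0.36 for G1/S and DNA replication, 0.43 and 0.30 for small and large ribosomal proteins, 0.38 for DNA repair, 0.56 for the erythroid list, 0.29 for cholesterol biosynthesis, 0.66 for myeloid progenitors and 0.75 for replication-dependent histones. They were -0.82 for mature neutrophils and monocytes, -0.66 for stromal and endothelial cells and -0.38 for megakaryocytes and platelets. With an estimated correlation 0 lists differed, the lowest adjusted p being 0.0865.

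In LSK cells, markers of several mature cell types were lower in KO as lists with camera at a preset correlation. With an estimated correlation or with fry 0 lists passed (lowest adjusted p = 0.632 and 0.654). The first WT library alone is argued against for the neutrophil and monocyte list, whose median was -0.51 without that library and still past the threshold at the preset correlation. It remains a candidate explanation for the B cell and T and NK lists, whose medians without it were 0.18 and 0.16. The gate is meant to remove lineage-positive cells, so other cell types would have to be carried over through the sort. Fewer such cells in the KO sorts cannot be told apart from a change within LSK cells, because 6 of 7 lists of other cell types had medians below 0 and the erythroid list ran from -0.032 to 0.55 over the fits without 1 library. A change through Anp32b within the gate also stays open and was not tested.

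In KU812 cells the glycolysis, G1/S, G2/M, ribosomal protein and cholesterol lists were lower together with camera at a preset correlation, and none passed with an estimated one (adjusted p from 0.392 to 0.513). With fry the glycolysis, G1/S and cholesterol lists did not pass (adjusted p = 0.104, 0.0720 and 0.145). A trend of fold change with expression level is argued against, since all 6 medians lay at or below the 0.01 percentile of 10000 expression-matched random lists. The scaling between libraries moves a list and its matched lists alike, so it cannot make the gaps between them. All 6 medians lay below the 2.5th percentile of their matched lists (gaps of -0.14 or lower). This rests on the same values as the expression-level test and adds no separate evidence. How far scaling set the medians themselves and the counts of genes that fell is not settled by it. The first shNC library alone does not account for the glycolysis and hypoxia list, whose median without it was -0.55 with its call in place. An effect of the hairpin on other transcripts, a difference in culture state and an effect of ANP32B stay open and were not tested.

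Echdc2, with a log2 fold change of 4.59 in KO LSK cells, lies on chromosome 4, as Anp32b does. A strain segment carried along with the knockout could raise the share of changed genes on that chromosome. With Anp32b and Echdc2 left out, 34 of 805 genes on chromosome 4 had an unadjusted p under 0.05 (4.22%), against 4.53% of genes elsewhere, an odds ratio of 0.928 with a 95% confidence interval from 0.632 to 1.32 (Fisher's exact test, one-sided p = 0.685). The interval includes values on both sides of 1, which keeps the explanation open, and no biological explanation was tested. Within 20 Mb of Anp32b, which starts at 46450902, 9 of 180 genes had an unadjusted p under 0.05. Echdc2, which starts at 108165437, lies outside that window.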

How the results depend on the processing

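With 2 libraries per group, single libraries set several results, and the cause was not tested. In LSK cells the 0 genes of edgeR became 15 with DESeq2, 2 with voom quality weights, and 0 to 830 without 1 library. They stayed at 0 with RLE factors, library totals only, no filter on low counts or no immunoglobulin genes. In KU812 cells the 2741 genes ran from 1413 to 4047 without 1 library. The 239 interaction genes became 570 with DESeq2 and 38 to 719 without 1 library, and the r of 0.0376 across genes ran from 0.0110 to 0.0619. With an estimated correlation 0 lists passed in LSK cells and 0 in KU812 cells, and with fry 0 and 8, of which 7 had also passed with camera.

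Pairing of the libraries by replicate number is not given by the labels, and 2 pairs per experiment leave it open (correlation of same-numbered deviations -0.0687 in LSK cells and 0.116 in KU812 cells). A replicate block gave 15 genes in LSK cells and 4164 in KU812 cells, and the neutrophil and monocyte list of KU812 cells did not pass under it (adjusted p = 0.0519).

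Over the fits without 1 library, values that changed direction ran from -1.31 to 0.16 (T and NK list), -0.032 to 0.55 (erythroid list), -0.69 to 0.18 (B cell list), -1.31 to 0.12 (Cdkn1a) and -1.27 to 0.058 (Derl3) in LSK cells. There the medians of the unfolded protein response list (-0.36 to 0.031) and the p53 list (-0.043 to 0.10) changed sign while their tests kept their direction. In KU812 cells they ran from -0.079 to 0.19 (ANP32A), -0.60 to 0.089 (CDKN1A), -0.14 to -0.022 (p53 list, whose test changed direction) and -0.11 to 0.040 (stem cell list), and the p53 median was 0.012 with library totals only. In LSK cells the neutrophil and monocyte, G2/M, stromal and stem cell lists passed in 12 of 12 gene-level settings with camera, and in KU812 cells 11 of the 13 lists in 11 of 11. Not run were a pseudocount, quantile scaling, median centring, a filter on mean values and limma-trend, which were planned for normalized values, and the use of genes listed in all files, which removes no gene.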

Other observations

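The test of unseen mast cell and eosinophil genes was chosen only after the pattern was seen, and the genes named in the first paragraph were chosen after their values were seen. In KU812 cells the list of STAT5 and BCR-ABL targets parted in the 2 directions, with 7 of 22 genes higher and 4 lower in shANP32B (9 and 4 adjusted over the list alone; median 0.17, adjusted p = 0.476, camera). The oncogene MYC fell from 1053 ± 49.9 to 594 ± 107 CPM (SD, n = 2 each; log2 fold change -0.82), and OSM, CCND3 and PIM1 fell by 0.66, 0.59 and 0.48 on the log2 scale. The cyclin gene CCND1, the kinase gene PIM2, the feedback regulator genes DUSP6, SOCS2, SPRED1 and SPRY4, and CCND2 rose, with log2 fold changes of 0.60, 0.61, 0.52, 0.41, 0.46, 0.74 and 1.72. In the integrated stress response list 5 of 27 genes fell and 0 rose in both counts, over all genes and adjusted over the list alone (median -0.16, adjusted p = 0.0764). DDIT4, which is induced by hypoxia and stress, fell by 1.54, and MTHFD2 and SHMT2 of mitochondrial one-carbon metabolism by 0.54 and 0.55. The fatty acid desaturase gene SCD fell by 2.47 and TCN1, a vitamin B12 binding protein of granules, by 2.33, while STAB1, a scavenger receptor gene, rose by 1.49.

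The share of counts from mitochondrial genes lay apart between the groups in both experiments, in opposite directions. It was lower in both KO than in both WT libraries and higher in both shANP32B than in both shNC libraries. With 2 libraries against 2 the smallest p of an exact two-sided test is 0.333, so the difference was not tested. In the nuclear-encoded oxidative phosphorylation list 0 of 38 genes passed in either experiment, over all genes or adjusted over the list alone.

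The fall of some eosinophil genes beside the rise of some mast cell genes in KU812 cells could be a shift between the programs that extends to members not seen before. Not all mast cell genes rose. KIT, already seen, stood at -0.32 and ENPP3, unseen, at -0.30, neither past the threshold. Over 13 unseen mast cell genes the mean log2 fold change was 0.41 and over 5 unseen eosinophil genes -0.19, a difference of 0.61 in the direction of the hypothesis (exact permutation test over genes, one-sided p = 0.179). HPGDS counts as unseen, though its log2 fold change of 0.42 is the median given for the basophil and mast cell list. HDC, MS4A2, FCER1A, MITF and ENPP3 count as unseen too, though they belong to that list and entered its test and counts. GATA2 belongs to the tested stem cell list. The unseen mast cell genes were therefore not fully held out. Of the 5 eosinophil genes 3 lay above 0, and without RNASE3 their mean was 0.56, above that of the mast cell genes. These genes are few, most mast cell members that had passed were already among those seen, and the test does not decide. Of the unseen genes 4 passed the threshold. The mast cell members SIGLEC6 and ADCYAP1 rose by 0.95 and 2.06 and the eosinophil member RNASE3 fell by 3.19 from a low level of 2.19 CPM, but the eosinophil member GPR34 rose by 1.75, against the hypothesis, while the histidine decarboxylase gene HDC stood at 1174 and 1175 CPM.

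In KU812 cells the real split called 2741 genes, and the other ways of splitting the 4 libraries into pairs called 0 genes each. These other splits put a control and a perturbed library in each group, so a real difference widens the spread within groups. They gave 173 and 65 genes at an unadjusted p under 0.05, where chance alone gives 826. Their 0 calls were thus set by the design and are no support for the 2741. In LSK cells the real split gave 657 genes at an unadjusted p under 0.05, and the other splits 455 and 748.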
